A study of Mus musculus with 2 samples.

How the data were processed

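MicroRNA sequencing (libraries with a size range under 30, per the labels) was run on neural tube dissected from mouse embryos of strain B6NCrl at 12.5 days of development. The labels describe 2 biological replicates of this single group, each from a pool of male and female embryos: 120 embryos in replicate 1 and 88 in replicate 2. No second tissue, age or treatment is part of these samples, so no comparison between conditions was made.

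For each library the authors deposited whole-number read counts per miRNA gene, without normalization, in 3 columns: both strands together and each strand alone. Per the descriptions deposited with the counts, they were made on the mm10 assembly with genome annotation M4 from the alignment of that library alone. The aligner, counter and adapter trimming are not given in the sources used here. In both libraries the both-strand count equalled the sum of the strand columns for every gene. The 4 rows that name no gene (unmapped reads, reads mapping to several places, reads on no feature, ambiguous reads) were left out of library totals and tests. Of all reads in the file of replicate 1, unmapped reads made up 27.3%, reads mapping to several places 27.0% and reads on no feature of the counted strand 8.04%. The same shares in replicate 2 were 20.0%, 28.6% and 4.45%. Ambiguous reads numbered 0 in both. Reads mapping to several places stand in a row of their own and are in no gene's count, which can lower the counts of miRNA genes whose mature sequence is present at more than 1 locus. A gene count holds both arms of a hairpin, so mature strands could not be told apart.

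The strand column with the higher total was taken as reads on the gene's own strand. Own-strand gene reads numbered 4802411 in replicate 1 and 4422853 in replicate 2, and a count of 0 allows up to 0.625 and 0.678 reads per 1000000 gene reads respectively (3 counts). Counts were divided by the own-strand total of the library to give reads per 1000000 gene reads (CPM), and the log scale used log2(CPM + 1). Intervals of shares are exact binomial (Clopper-Pearson, 95%). PCR reads without molecular identifiers are not independent molecules, so intervals, floors and the exact binomial test between the libraries cover counting error only. Errors are the SD of the 2 replicates.

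Gene symbols, coordinates and gene context were taken from GENCODE M21, which uses the same assembly (GRCm38, mm10) but a later release than the counts. Of 1973 gene identifiers, 1894 matched by identifier without version, and none of the 79 unmatched identifiers reached 10 reads in both libraries. Genes were called repeated when their M21 hairpin sequence shared 20 bases with another miRNA hairpin. The genome sequence was not used here, so copies outside annotated miRNA genes were not searched.

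Before the data were examined, 16 gene lists with 180 entries, the detection rule, the tests and the rule for named genes were fixed. Of the entries, 167 matched a counted gene by symbol and the others were not analysed as list members. Matching used the listed symbols alone, so an entry whose gene carries another symbol was missed. Mir134 stands in both the neuronal and the Dlk1-Dio3 list. A gene was detected with at least 10 reads in both libraries. The genes named are the 20 with the highest mean CPM, up to 4 members of each list with the highest mean CPM, and the 10 with the largest ratio between libraries among genes past the test with a mean CPM of at least 10. Other genes named were chosen after their values were seen, as members of the same families, clusters or lists. The median log2 CPM of each list's detected members was given as its percentile among 10000 random lists of as many detected genes. Members that were not detected are in none of these medians, which can raise them.

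Because there are no 2 groups, edgeR's quasi-likelihood test was not applied. The replicate error was summarised by the common coefficient of variation from edgeR 4.0.16 (R 4.3.3, intercept-only model, TMM scaling, detected genes). The 2 libraries were compared gene by gene with a two-sided exact binomial test given the TMM-scaled totals, with Benjamini-Hochberg adjustment over detected genes, a threshold of 0.05 and at least 2-fold. This test compares the libraries and not conditions. The median ratio of each list with at least 3 detected members was placed among 10000 random lists matched on mean expression, each member drawn from its 40 nearest genes in abundance. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Figures used matplotlib 3.10.9.

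The tests were checked on simulated data. In Poisson counts for 371 genes, 98.5% of genes set 3-fold apart and 100% of those set 4-fold apart were called in the right direction. A 1.5-fold difference was called in 1.49% and no difference in 1.17%. Negative binomial counts were simulated with no difference and the coefficient of variation of these libraries. Of 364 genes, 53.3% passed the exact binomial test without a fold minimum, and 0.824% with the 2-fold minimum. That coefficient was estimated from these same libraries, so it holds any difference between the pools as well as replicate error. The alternatives tried were both-strand counts, leaving out genes numbered as repeated loci, other denominators, other count minimums and pseudocounts, library totals or DESeq2 1.42.0 size factors in place of TMM, other fold minimums, and leaving out each replicate.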

Results

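MicroRNA genes were quantified in embryonic mouse neural tube, the precursor of the brain and spinal cord, at 12.5 days of development. The group holds 2 biological replicates, pools of 120 and 88 embryos, with 4802411 and 4422853 reads assigned to miRNA genes on their own strand. The comparisons this design allows are those of read counts among miRNA genes within the tissue and those between the replicate libraries. With 2 libraries, no exact test of an order between genes can go below p = 0.5, so ratios are given with their SD between libraries.

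Of 1973 miRNA genes counted, 371 were detected with at least 10 reads in both libraries and 1237 had no read in either. The reads were concentrated in few genes. The 2 most abundant held 32.8% ± 0.882 of the gene reads (SD, n = 2), the 10 most abundant 59.5% ± 0.742 and the 20 most abundant 72.0% ± 0.805. By GENCODE M21 on the mm10 assembly, whose coordinates are given throughout, 166 of the detected genes lie in an intron of another gene on their strand, 95 overlap an exon, and 110 have no other gene on their strand.

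**Figure D1:**
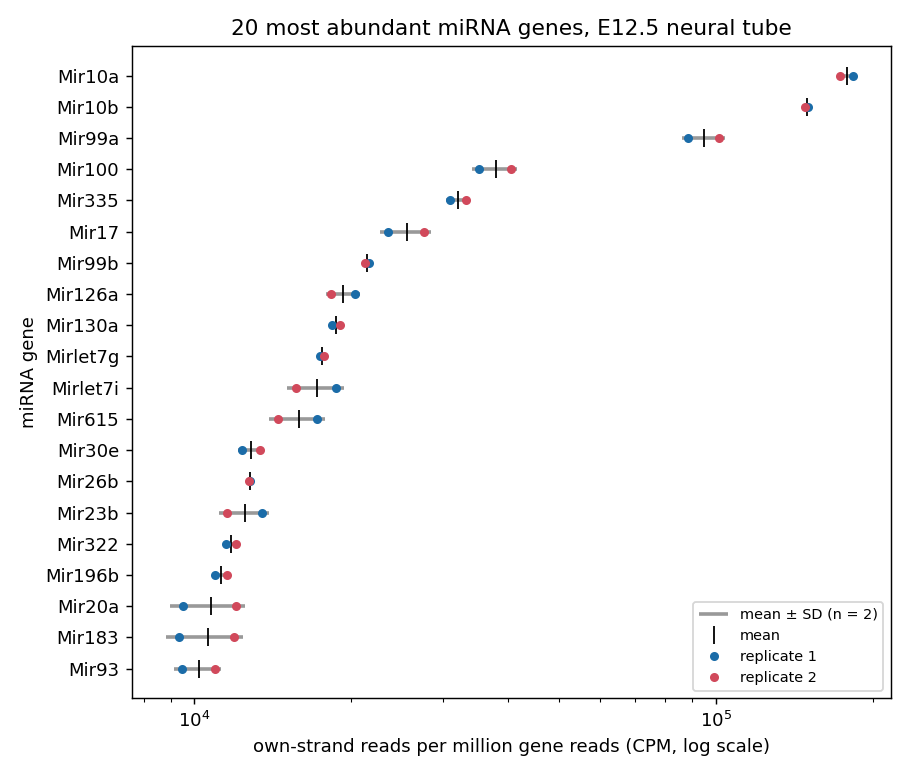
Own-strand reads per 1000000 gene reads (CPM, log axis) of the 20 miRNA genes with the highest mean, in each replicate (points), with the mean (tick) and SD (grey bar, n = 2). Mir10a (178286 CPM) and Mir10b (149286 CPM) lie above Mir99a (94942 CPM) in both replicates.

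The miRNA genes of the Hox clusters, which carry the transcription factor genes that pattern the body axis, held the highest share of the 16 lists. Their 6 members held 35.6% ± 1.07 of all gene reads (SD, n = 2), and Mir10a and Mir10b were the 2 genes that held 32.8%. Without Mir10a the Hox share was 21.7% ± 0.606 and that of the neuronal list 22.1% ± 1.39, which differed by less than their spread. With reads mapping to several places in the denominator, the Hox share was 21.4%, the neuronal 10.9% and that of the Mir17 cluster list 4.03%. Dlk1-Dio3 then held 2.83% and let-7 2.46%. This lowers every share and CPM of a library by the same factor, so it cannot change the order of the lists within a library. Assigning those reads to genes could change it. Of 35 neuronal members 22 share 20 bases with another miRNA gene, against 2 of 6 Hox members. As a share of gene reads alone, the Hox list held 36.4% in replicate 1 (95% interval 36.3 to 36.4) and 34.9% in replicate 2 (34.8 to 34.9). Mir10a, on chromosome 11 at 96317165 to 96317274, 0.993 kb from Hoxb4, reached 178286 ± 7283 CPM (n = 2). Mir10b, on chromosome 2 at 74726070 to 74726137 in an intron of Hoxd3 and Hoxd4, reached 149286 ± 1538 CPM. The ratio of Mir10a to Mir10b was 1.19 ± 0.0365 and thus above 1 by more than its spread. Mir615, in an intron of Hoxc5 on chromosome 15 (103014910 to 103015001), had 15833 ± 1929 CPM, and Mir196b, overlapping an exon of Hoxa9 on chromosome 6 (52230081 to 52230165), 11225 ± 420.1 CPM. All 6 members were detected. The median of the list lay at percentile 100 of random lists of detected genes. Mir196a-1 and Mir196a-2 share hairpin sequence with each other, and Mir196b outnumbered Mir196a-2 by 7.07 ± 1.79 times in uniquely assigned reads.

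The list of neuronal and neural progenitor miRNA genes held 18.2% ± 1.30 of the reads, with 32 of 35 members detected and a median at percentile 92.4. Most of this share came from 3 members of the related Mir99 and Mir100 genes, which are not specific to neurons. Mir99a, in an intron of Mir99ahg on chromosome 16 (77598936 to 77599000), had 94942 ± 9040 CPM (n = 2). Mir100, on chromosome 9 (41531425 to 41531504), had 37798 ± 3700 CPM, and Mir99b, in an intron of Spaca6 on chromosome 17 (17830188 to 17830257), 21419 ± 222.5 CPM. The ratio of Mir99a to Mir100 was 2.51 ± 0.00678. Without these 3 genes the list held 2.76% ± 0.0518. Mir181c, in an intron of Nanos3, followed with 6879 ± 741.6 CPM. Mir137, a regulator of neuronal differentiation, had 2809 ± 379.0 CPM, and Mir153 807.1 ± 1.17 CPM. The genes of the classical neuronal miRNA Mir124a had few uniquely assigned reads: 9.71 ± 1.58 CPM for Mir124a-2, 1.85 ± 0.261 for Mir124a-1 and 1.52 ± 0.0885 for Mir124a-3. Mir9-3, a copy of the neural progenitor miRNA gene Mir9, had 283.1 ± 21.1 CPM and Mir9-2 3.95 ± 2.07. Each of these genes shares 20 bases of hairpin with 2 other miRNA genes, and reads that map to several places are in none of these values. Mir344 had no read in either library, and it too shares sequence with other miRNA genes.

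**Figure D2:**
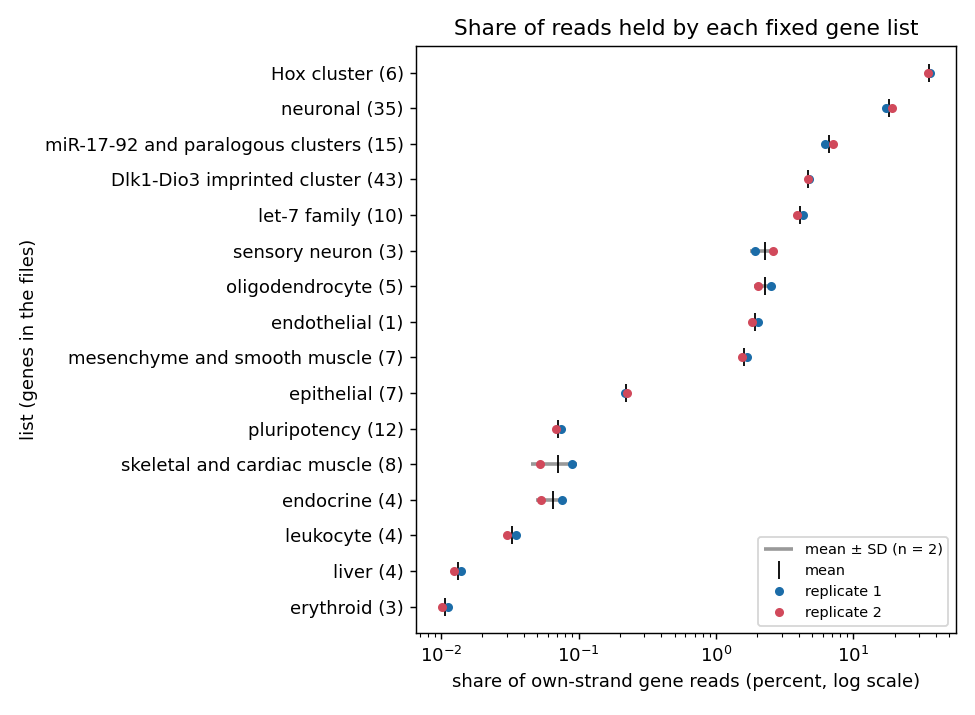
Share of own-strand gene reads (percent, log axis) held by each of the 16 gene lists, in each replicate (points), with the mean (tick) and SD (grey bar, n = 2). The Hox cluster list leads with 35.6%, the neuronal list follows with 18.2%, and the erythroid list is lowest with 0.0107%.

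The Mir17 cluster and its 2 paralogous clusters, which are active in proliferating progenitors, held 6.69% ± 0.670 of the reads, with 15 of 15 members detected and a median at percentile 99.2. Mir17, in an exon of Mir17hg on chromosome 14 (115043671 to 115043754), had 25531 ± 2885 CPM. Mir20a, from the same transcript (115044157 to 115044263), had 10738 ± 1772 CPM, and Mir93 and Mir106b, within Mcm7 on chromosome 5, 10190 ± 1049 and 7392 ± 883.5 CPM. Members of the same primary transcript differed widely in reads. Mir17 outnumbered Mir18 by 5.27 ± 0.00988 times and Mir19a by 241.4 ± 3.44 times. Mir19a shares no 20 bases with another annotated miRNA gene. How evenly the libraries captured different sequences was not measured, and the SD does not cover it, so these are ratios of reads and not of molecules.

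The let-7 family, whose mature forms accumulate as tissues differentiate, held 4.10% ± 0.310 of the reads, with 10 of 10 members in the files detected. Mirlet7g, in an intron of Wdr82 on chromosome 9 (106178840 to 106178927), had 17546 ± 223.4 CPM. Mirlet7i, on chromosome 10 (122985640 to 122985724), had 17168 ± 2154 CPM, and their ratio of 0.979 ± 0.135 did not differ from 1 by more than its spread. Mirlet7d had 2541 ± 588.3 CPM and Mir98 1672 ± 221.7. The 5 members that share sequence with another gene had at most 333.5 CPM, the value of Mirlet7f-2.

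The imprinted Dlk1-Dio3 region on chromosome 12 held 4.70% ± 0.0642 of the reads, with 42 of 43 members detected and a median at percentile 98.0. Mir487b (109727333 to 109727414) led with 8163 ± 26.6 CPM, followed by Mir369 in an exon of Mirg with 4867 ± 249.5, Mir411 with 4696 ± 481.8 and Mir127 with 4692 ± 139.0. Mir654 had no read in either library. The pluripotency list held 0.0711% ± 0.00414 of the reads, with 7 of 12 members detected. Its reads came mainly from the Mir302 genes on chromosome 3, with 248.2 ± 9.78 CPM for Mir302a, 217.9 ± 6.33 for Mir302d, 188.9 ± 22.0 for Mir302b and 28.9 ± 2.29 for Mir302c. Mir367, from the same cluster, had 0 reads in both libraries, which allows up to 0.625 CPM in replicate 1 and 0.678 in replicate 2. Mir290a also had 0 reads. Mir487b, Mir411, Mir302a and Mir302b each share 20 bases with 1 other miRNA gene, and reads that map to several places are not in their values.

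The oligodendrocyte list held 2.26% ± 0.350, of which most came from Mir23b (12502 ± 1377 CPM) and Mir23a (4059 ± 638.0), genes that many cell types express. Without Mir23a and Mir23b it held 0.602% ± 0.149. Mir219a-2 on chromosome 2 (29845631 to 29845727) had 5544 ± 1479 CPM and Mir219a-1 395.2 ± 7.05, and Mir338, in an intron of Aatk, 76.8 ± 1.20. The Mir23 and Mir219a genes each share 20 bases with 1 other miRNA gene.

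Markers of cell types outside the neural epithelium were measured in the same way. The sensory neuron list, a cluster on chromosome 6 active in sensory ganglia and sense organs, held 2.26% ± 0.499, with Mir183 (30169668 to 30169737) at 10623 ± 1787 CPM, Mir182 at 8703 ± 2658 and Mir96 at 3295 ± 543.9. The endothelial gene Mir126a, in Egfl7 on chromosome 2 (26591357 to 26591429), held 1.93% ± 0.145, or 19281 ± 1447 CPM. The mesenchyme and smooth muscle list held 1.61% ± 0.0820, with Mir214 at 5533 ± 986.9 CPM, Mir143 at 5340 ± 232.8, Mir140 at 4900 ± 69.9 and Mir199b at 231.9 ± 10.7. Mir199b shares 20 bases with 2 other miRNA genes, and reads that map to several places are not in its value.

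The remaining marker lists held far smaller shares. The epithelial list held 0.222% ± 0.00422, with Mir203 at 1100 ± 137.6 CPM, Mir205 at 481.6 ± 15.7, Mir429 at 352.9 ± 56.9 and Mir200c at 132.2 ± 22.7. The muscle list held 0.0710% ± 0.0258, most of it from Mir206 (640.4 ± 241.3 CPM). Mir208b had 37.9 ± 13.9 CPM, Mir133b 11.7 ± 3.46 and Mir208a 10.7 ± 2.46, and Mir133a-1 and Mir133a-2 had 0 uniquely assigned reads. Mir133b, Mir133a-1 and Mir133a-2 each share 20 bases with 2 other miRNA genes. Mir1a-1, with 1 read in replicate 1 and 0 in replicate 2, shares 20 bases with 1 other. Reads that map to several places are in none of these values, so counts at or near 0 do not show that these miRNAs are absent. The list named endocrine held 0.0648% ± 0.0161, with Mir375 at 290.3 ± 101.6 CPM, Mir217 at 231.9 ± 56.1, Mir216b at 71.8 ± 8.24 and Mir216a at 53.9 ± 5.28. That name was set beforehand, and whether all 4 genes mark endocrine cells was not tested. The leukocyte list held 0.0327% ± 0.00326, with Mir223 at 186.0 ± 22.3 CPM, Mir155 at 123.2 ± 11.2, Mir150 at 16.5 ± 0.653 and Mir146b at 1.20 ± 0.223. The leukocyte share was 0.0581% with the opposite-strand reads at the place of Mir142 added, an alternative chosen after the data were seen. The list entry Mir146a matched no symbol, and the gene with the symbol Mir146 (36.3 ± 17.5 CPM) is not in these shares. The liver list held 0.0132% ± 0.00115, with Mir192 at 62.7 ± 4.41 CPM, Mir194-2 at 46.4 ± 2.97, Mir122 at 23.1 ± 12.9 and Mir194-1 at 0.217 ± 0.0126. The erythroid list held 0.0107% ± 0.000712, with Mir451a at 72.7 ± 5.58 CPM, Mir144 at 17.3 ± 3.62 and Mir486 at 16.8 ± 5.16. Mir146b, Mir146, Mir194-1, Mir194-2 and Mir486 each share 20 bases with 1 other miRNA gene. Their values too lack the reads that map to several places. The ratio of Mir126a to Mir451a was 265.3 ± 0.470.

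The libraries ranked the miRNA genes almost alike. Across the 371 detected genes, which are not independent replicates, Pearson's r of log2(CPM + 1) was 0.994 and Spearman's rho 0.992. Both had a permutation p of 1e-05, the smallest that 100000 permutations can give, also after Benjamini-Hochberg adjustment over these 2 relations. This p speaks only against unrelated rankings and does not measure how closely the libraries agree. The common coefficient of variation was 16.3%, which corresponds to an SD of 0.33 for a log2 ratio of the 2 libraries. The libraries were counted as separate replicates, since the labels give them as separate pools. The median absolute log2 ratio was 0.24, and 329 of the 371 genes lay within 1.5-fold.

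Between the libraries, 10 genes were at least 2-fold apart past the exact binomial test, 9 of them higher in replicate 1. They were genes of low abundance, with a median of 74 reads in replicate 1. Mir6240, on chromosome 5 (114851948 to 114852064), had 226 reads in replicate 1 and 46 in replicate 2, a 4.40-fold difference. Mir6236 on chromosome 9 (110281287 to 110281409) was 2.81-fold higher with 524 against 167 reads. Gm26117, in an exon of Adgrb1, was 2.97-fold higher, the liver gene Mir122 2.24-fold with 155 against 62 reads, and Mir490, in an intron of Chrm2, 2.01-fold. Mir6538, Mir294, Mir1191 and Gm23388 were also higher in replicate 1, each with a mean below 10 CPM. Mir190b was 2.09-fold higher in replicate 2, with 60 against 32 reads. With a minimum of 100 reads in both libraries, and scaling over those genes, 2 genes were at least 2-fold apart, Mir6236 and Mir146, of which Mir146 is not among the 10. Among named genes under 2-fold, Mir146 was 1.98-fold, Mir7j 1.88-fold and Mir505 1.73-fold higher in replicate 1, and Mir138-1 1.91-fold higher in replicate 2. Without a fold minimum 197 genes passed, 97 higher and 100 lower in replicate 1. They were 53.1% of those tested, while 53.3% passed in counts simulated with no difference and the coefficient of variation of these libraries. The balance moved with the setting, to 111 higher and 82 lower with library totals in place of TMM and 83 and 103 with at least 1 read in either library. The 10 genes were 2.70% of those tested, and in counts simulated with no difference and the coefficient of variation of these libraries 0.824% of genes passed at 2-fold. The simulated coefficient of variation came from these same libraries, so the match of 53.1% and 53.3% was built in. It does not show that the pools are alike. The test covers counting error alone, so passing it does not show a difference between the pools beyond replicate error.

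**Figure D3:**
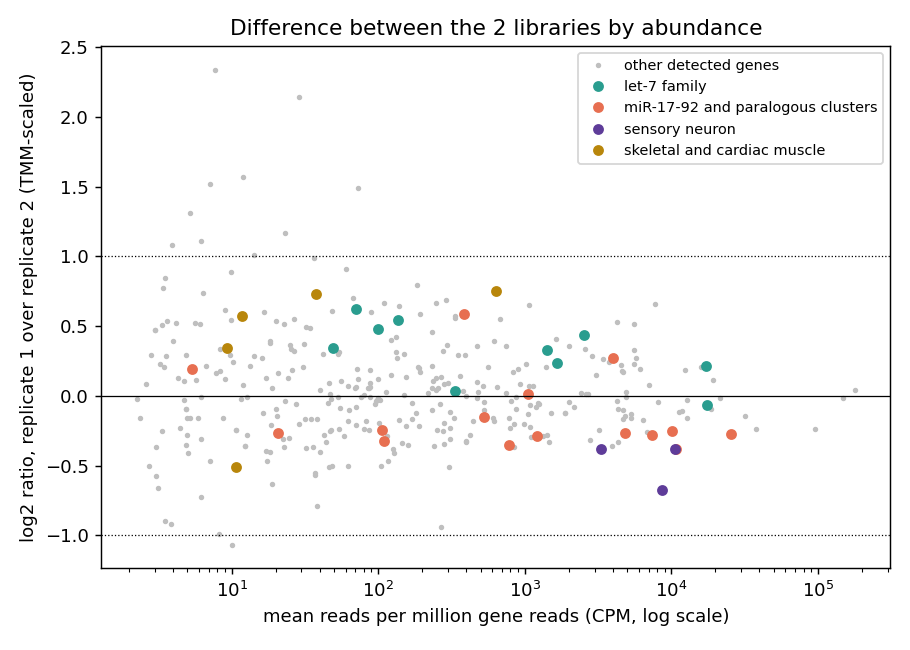
Log2 ratio of replicate 1 over replicate 2 (TMM-scaled) against mean CPM (log axis) for the 371 detected genes, with members of 4 lists coloured and dotted lines at a 2-fold difference. Members of the let-7 list (median 0.34) and the muscle list (median 0.57) lie mostly above 0, those of the Mir17 cluster list (median -0.26) mostly below, and the 3 of the sensory neuron list (median -0.38) all below.

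Of 15 lists with at least 3 detected members, 4 had a median ratio outside the central 95% of random lists matched on abundance. The counts of members past the exact binomial test given below have no fold minimum. Of all detected genes 53.1% passed it, and 53.3% did in counts simulated with no difference. The simulation took its coefficient of variation from these same libraries, so this match was built in. The counts of members past the test therefore cannot tell a difference between the pools from replicate error. The let-7 family was higher in replicate 1 (median log2 ratio 0.34, percentile 99.9), with 8 members higher and 1 lower past the exact binomial test, and 9 past it adjusted over the list alone. Mirlet7d was 1.35-fold and Mirlet7i 1.16-fold higher in replicate 1. The 1 member lower there was Mirlet7g (log2 ratio -0.06), the most abundant of the list. The skeletal and cardiac muscle list was also higher there (0.57, percentile 98.5), with 2 of 5 detected members higher past the test, and 2 adjusted over the list alone. Mir206 was 1.68-fold and Mir208b 1.66-fold higher. Mir208a lay on the other side (log2 ratio -0.51, 43 reads in replicate 1 against 55) and did not pass the test. Without the 2 muscle genes that share 20 bases with a longer transcript, the median of the 3 left was 0.34 at percentile 90.8, inside the range, in an alternative also chosen later. The Mir17 cluster list was lower in replicate 1 (-0.26, percentile 0.05), with 10 members lower and 2 higher, and 12 past the test adjusted over the list alone. The sensory neuron list was lower as well (-0.38, percentile 0.04), with 3 of 3 members lower past the test and 3 adjusted over the list alone. Genes of 1 cluster are not independent, so the percentiles describe these libraries and are not p-values. The neuronal list (-0.03, percentile 28.2), the Hox list (0.04, percentile 77.8) and the Dlk1-Dio3 list (-0.03, percentile 28.7) lay inside the range, as did the oligodendrocyte, pluripotency, erythroid, leukocyte, mesenchyme, epithelial, liver and endocrine lists. Past the test, 9 neuronal genes were higher and 14 lower in replicate 1 (24 adjusted over the list alone), 3 Hox genes higher and 2 lower (5 adjusted over the list alone), and 10 Dlk1-Dio3 genes higher and 16 lower (26 adjusted over the list alone). Of the other lists, the epithelial had 3 higher and 2 lower, the mesenchyme 1 and 2, the oligodendrocyte 3 and 0, the pluripotency and endocrine 2 and 0 each, and the erythroid, leukocyte, liver and endothelial 1 and 0 each, with the same totals adjusted over the list alone. Without the genes numbered as repeated loci, the let-7 median fell to 0.25 at percentile 96.6 and so inside the range. The share of reads on no feature of the counted strand was 8.04% in replicate 1 and 4.45% in replicate 2.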

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

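All tests in this part were chosen after the counts had been seen. The first signal outside the main measurement is the column of reads on the strand opposite to the gene, which lies above what a count of 0 allows. The column held 84152 reads in replicate 1 and 66438 in replicate 2, and 11 genes with at least 100 such reads in both libraries held 99.6% of them in each. In the order replicate 1 then replicate 2, the opposite-strand reads were 29204 and 21001 over Gm24321 (opposite Mir409), 21418 and 14247 over Gm25927 (opposite Mirlet7e), and 8391 and 8046 over Gm25252 (opposite Mir376a). Over Gm24083 (opposite Mir191) they were 7915 and 6787, over Gm25301 (opposite Mir378a) 6472 and 5818, over Mir299b (opposite Mir299a) 4254 and 3767, and over Gm25750 (opposite Mir380) 3486 and 3916. Over Mir142b (opposite Mir142) they were 1230 and 1118, over Mir497b (opposite Mir497) 1024 and 904, over Gm25641 (opposite Mir9-1) 258 and 448, and over Mir3074-1 (opposite Mir24-1) 181 and 147. The partner names and places are those of GENCODE M21, a later release than the counts.

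Strand errors of the library preparation are argued against as the whole cause, because 10 of the 11 genes had more opposite-strand than own-strand reads. Among 151 genes with at least 1000 own-strand reads in both libraries, 150 had opposite-strand reads under 1% of their own-strand reads. A candidate explanation is that the reads come from the miRNA gene annotated on the other strand, since 11 of the 11 genes overlap such a gene, against 21 of the other 1883 matched genes (Fisher exact p = 4.71e-21). Antisense transcription of the counted genes themselves stays open for lack of read sequences, and no biological explanation was tested. If the reads are the partners' own, Mirlet7e would stand at 3841 ± 875.8 CPM and Mir409 at 5415 ± 942.4 (SD, n = 2), and the shares would be 4.47% for the let-7 family and 5.54% for the Dlk1-Dio3 list.

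The second signal is the reads that map to several places and are in no gene's count, 3448592 in replicate 1 and 2698981 in replicate 2, or 0.718 and 0.610 per assigned read. In the let-7 family, the 5 members that share 20 bases with another miRNA gene had a median of 99.1 CPM and at most 333.5, while the 5 others had a median of 2541 and at least 1420 (exact permutation p = 0.0079), which restates the difference that prompted the test and is no separate evidence. Across all lists, 56 members with shared sequence differed from 110 without it by -2.40 in mean log2(CPM + 1), with medians of 120.2 and 344.5 CPM (permutation p = 0.00016), and without the let-7 family 51 members differed from 105 by -2.29 (permutation p = 0.00052). The differences across lists are consistent with the loss of reads that map to several loci, which may also account for the low values of the Mir124a and Mir9 genes. A truly lower level of those genes stays open, since the unassigned reads are not divided by gene, and no biological explanation was tested.

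Reads on no feature of the counted strand, also outside the main measurement, numbered 1025049 in replicate 1 and 419270 in replicate 2. Per assigned read this was a 2.25-fold difference. By this definition, reads opposite to a counted gene can be among them.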

How the results depend on the processing

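The opposite-strand additions, the lists without their dominant genes and those without genes that share sequence with longer transcripts were chosen after the data were seen. The share of the 10 most abundant genes (59.5%) was 58.5% in both-strand counts, 61.0% without genes numbered as repeated loci, 35.8% with reads mapping to several places in the denominator and 52.8% without Mir10a, and it ranged from 59.0% to 60.0% when 1 replicate was left out. The Hox share (35.6%) was 21.4% with reads mapping to several places in the denominator and 21.7% without Mir10a, and 34.9% to 36.4% when 1 replicate was left out. Detected genes numbered 606 with at least 1 read in both libraries, 269 with at least 100, 382 in both-strand counts, 324 without repeated loci and 381 to 399 in single replicates. The coefficient of variation of 0.163 from edgeR was 0.0802 as the median gene-wise value of DESeq2, a different summary whose cause of difference was not tested, and 0.152 to 0.165 otherwise. In place of 10 genes at least 2-fold apart there were 2 with at least 100 reads in both, 33 at 1.5-fold and 197 without a fold minimum, and 10 to 13 under the other settings. Without a fold minimum the split of higher and lower genes (97 and 100) was 102 and 80 with at least 100 reads, 84 and 74 without repeated loci, 100 and 102 in both-strand counts and 95 and 101 with DESeq2 size factors. The count of lists that differed (4) was 2 without genes that share sequence with a longer transcript, of which the sensory neuron list lost no member, and 3 or 4 under the other settings run. A list with fewer than 3 members past a filter was not placed under it, and the ratio of a list that lost no member to the filter on longer transcripts is not counted for it. The correlation r stayed between 0.993 and 0.995. Of the alternative list ratios 75 kept their side of the range and 2 did not, the let-7 median without repeated loci (0.25) and the muscle median without genes that share sequence with a longer transcript (0.34). For the 10 genes named for their ratio, 54 alternative values kept direction and significance. No scaling moved the median of all genes by over 0.1 (log2), the largest shift being 0.04. Of the alternative list shares other than those of single replicates, which always lie within the SD of 2 values, 40 moved by more than the replicate SD and 32 did not. Among the first was the leukocyte share, which was 0.0581% with the opposite-strand reads at Mir142 added. Depth limits statements on genes under 10 reads. No paired analysis was possible because the series holds a single group.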

Other observations

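The tests of GC content and of longer RNAs reported here were chosen before their results were seen, and the test of the Mir17 transcript and those of longer RNAs in parts of the lists after. Genes outside the fixed lists held 22.2% ± 0.392 of the reads (SD, n = 2), and those named here were chosen after their values were seen. Mir335, in an intron of the imprinted gene Mest on chromosome 6 (30741299 to 30741396), was the fifth most abundant gene with 31984 ± 1592 CPM. Mir130a had 18715 ± 471.0 CPM, Mir30e in an intron of Nfyc 12833 ± 739.3, and Mir26b in an intron of Ctdsp1 12751 ± 66.1. A cluster of 7 genes on the X chromosome (53047997 to 53054349) held 1.45% ± 0.00944 of the reads, mainly from Mir322 with 11750 ± 388.9 CPM. Mir296 and Mir298, adjacent genes near the imprinted Gnas locus on chromosome 2, had 4559 ± 583.4 and 3788 ± 522.0 CPM.

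Introns of Sfmbt2 on chromosome 2 hold 107 of the counted miRNA genes, of which 9 were detected. They held 0.449% ± 0.0109 of the reads, and 83.0% ± 0.457 of these came from the 3 genes Mir467d (1406 ± 168.1 CPM), Mir467c (1258 ± 11.3) and Mir467e (1060 ± 45.6). Of the 107 genes, 104 share 20 bases with another miRNA gene, and reads that map to several places are in none of these values.

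In uniquely assigned reads, Mir92-1 went against the other genes of its transcript in the comparison of the libraries. Of the 6 members of the Mir17 cluster, 4 were lower in replicate 1 past the exact binomial test, with log2 ratios of -0.27 for Mir17 and Mir18, -0.38 for Mir20a and -0.24 for Mir19a, and Mir92-1 was higher (0.27). Of its relatives at other loci, Mir92-2 (0.59) and Mir92b (0.66) were higher past the test, Mir25 (-0.15) was lower past it, and Mir363 (0.01) did not pass. Mir92-1 and Mir92-2 each share 20 bases with 1 other miRNA gene, while Mir17, Mir18, Mir20a and Mir19a share none. Reads that map to several places are thus missing from the counts of Mir92-1 and Mir92-2.

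For the differences between the libraries, the trend of the log2 ratio on hairpin GC content (Spearman rho 0.125 across 371 genes, permutation p = 0.0166) is argued against as the whole cause, since with it removed 8 of the 10 genes stayed at least 2-fold apart and 4 of the 4 lists stayed outside the random range. Fragments of longer RNAs remain a possible explanation for the 10 genes, of which 5 share 20 bases with a longer transcript against 108 of 361 other detected genes (Fisher exact p = 0.18). A gene's own host transcript counted as a longer transcript here. Only transcripts of GENCODE M21 were searched, so fragments of RNAs outside that annotation could not be seen for any of the 10 genes. Without the genes that share such sequence, the Mir17 cluster list stayed outside the range (1 of 1, -0.29 over the 5 members left, percentile 1.43). This argues against fragments of annotated longer RNAs only for the 5 members left, as a set. Members in an exon of their host, such as Mir17, Mir18 and Mir20a in Mir17hg, are not tested by leaving such genes out. For the let-7 list (2 members left) and the muscle list (3 left, percentile 90.8), of which 0 stayed outside, too few members remain to decide. The sensory neuron list, the other of the 2 lists outside, lost no member and so was not tested by leaving genes out. Of its 3 members, 0 share 20 bases with a longer transcript, which argues against fragments of annotated RNAs there. These genes have no other annotated gene on their strand, so fragments of an unannotated host transcript stay open. A lower level of the whole Mir17 transcript in replicate 1 cannot be told apart from a shift of single members. Measured from 0, the 0.27 of Mir92-1 lies within the SD of 0.33 that the coefficient of variation gives for a log2 ratio. The values of Mir17, Mir18 and Mir19a lie within it too, so replicate error could account for single members on either side. Mir92-1 is further than that SD from the members lower past the test, but 1 member does not decide the question. No biological explanation was tested, as both libraries belong to 1 group.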
